A study of Mus musculus with 16 samples.

How the data were processed

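RNA of splenic B cells from AM14 mice was read on 16 Agilent mouse arrays of 2 colours, 1 array for each of 4 genotypes (WT, Tlr7 knockout, Tlr9 knockout and double knockout) at each of 4 times (0, 6, 24 and 42 h with PL2-3). Per the labels, total RNA was prepared with Trizol and RNeasy columns, copied to cDNA from a T7 primer and amplified with labelled CTP. The sample carried Cy5 and the reference, a pool of unstimulated B cell RNA from all genotypes, carried Cy3. There was no dye swap. How the mice were bred, their sex and age, how the B cells were purified and cultured, the PL2-3 dose and whether RNA was pooled over mice are not given in the sources used here.

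Per the file headers, the images were read with Agilent Feature Extraction 10.1.1.1 on a design annotated on the mm9 build, with 62976 spots per array, of which 3671 are controls. The deposited spot intensity is the mean foreground and the median local background of each colour before any correction. The deposited processed signals, also an intensity, were background-subtracted, spatially detrended and dye-normalized by Feature Extraction, with surrogate values for dim spots. Per the file headers, the log ratio column is the log10 of Cy5 over Cy3. The authors' series table holds, within 6e-04 in 100% of the spots checked, the log10 of the ratio of the processed signals, and it differs from the log ratio column (lowest correlation over arrays 0.9209). Other deposited columns are flags of 0 or 1, such as whether a spot is well above background, saturated or uneven. No spot was saturated.

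Values were computed from the unprocessed intensities in R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8). Background was corrected with normexp (offset 50), the colours were normalized within each array by loess, and values are log2 of Cy5 over Cy3, relative to the pool. Control spots were left out, spots with an outlier flag were set to missing and repeated probes were averaged. Of 55681 distinct probes, 27235 were named by the accession they target, 3581 by symbol and 565 by an older symbol from a table of mouse RefSeq genes (assembly GRCm38, used only for names and for which genes lie near each other), and 24300 had no symbol in it. Each gene was represented by its brightest probe. A probe was tested when it was well above background in either colour on at least 3 arrays of the comparison. For a gene not above background in 1 of the compared groups, the fold was computed in the Cy5 channel, after normalization between arrays with Aquantile, against the background level and is given as "at least". Depth in arrays is signal over background, and the number of arrays limits the precision.

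Each gene was fitted with limma (lmFit and eBayes), 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on adjusted p. The responses at 6, 24 and 42 h used the 12 arrays of WT, Tlr7 knockout and Tlr9 knockout with genotype as a term (6 residual degrees of freedom), so that the genotypes stand in for replicates. Genotype comparisons used the 12 stimulated arrays with time as a term. The double knockout was set against the other 3 genotypes (8 residual degrees of freedom), and Tlr9 knockout against WT, Tlr7 knockout against WT and Tlr9 knockout against Tlr7 knockout were taken from 1 fit. Response differences used all 16 arrays, each genotype's stimulated arrays less its 0 h array. The single 0 h array of each genotype adds nothing to the residual spread of that fit. It was assumed to vary like the stimulated arrays. These make 10 tested comparisons. Single arrays were compared as the number of genes at least 2-fold (log2 of 1) apart, and as list medians set against 10000 random lists drawn from the same 10 bins of mean brightness, with no p-value. Probes of the deleted genes were compared with a 2-sided exact permutation test.

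Gene lists, tests, comparisons and most alternatives were fixed before the data were examined. The 19 lists cover plasma cells, the endoplasmic reticulum and secretion, mature B cell identity, cell cycle, interferon-stimulated genes, NF-κB and activation, immediate early genes of the antigen receptor, cytokines and chemokines, class switching and T-bet, apoptosis and survival, the nucleic acid TLR pathway, MYC and ribosome biogenesis, glycolysis, oxidative phosphorylation, markers of T cells, myeloid cells, NK and plasmacytoid cells and erythroid cells, and marginal zone and B1 genes. Cr2 stands on the lists of mature B cell identity and marginal zone genes, and Cd5 on those of T cells and marginal zone genes. Lists were tested with camera (preset correlation 0.01, and with an estimated correlation), adjusted over the 19 lists. The test fry, which does not set a list against the other genes, was planned and run beside it with the same adjustment. Its results are given for 6 h only. A list is said below to pass or to be called by camera. Genes were named by rule: the 10 largest rises and falls past the threshold that go the same way in every genotype or at every time compared, up to 4 members of each list with the smallest adjusted p (or the 2 largest differences if none passed), and a fixed set of B cell genes (among them Tlr7, Tlr9, Prdm1, Xbp1, Irf4, Sdc1, Jchain, Bcl6, Pax5, Myc, Cd69, Cd86, Il6, Il10 and Bcl2l11). Genes known only by a clone or model name and immunoglobulin segments were passed over. The text leaves out some names and says where it adds others.

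Alternatives were no background correction, the deposited log ratios, the series table, scale and Aquantile normalization between arrays, median centring in place of loess, no filter or a stricter filter on dim probes, the mean over a gene's probes, eBayes with trend and robust, a 2-fold minimum, array weights, leaving out each array in turn, no genotype or time term, all 16 arrays, the own 0 h array subtracted, and the slide as a block. Chosen after the data were seen were the exchange of the Tlr9 knockout 24 h and 42 h labels, fits without the Tlr9 knockout arrays and fits within 1 slide. The fits were tested on simulated data with the same design and each gene's fitted spread. The noise was drawn independently for each gene and array. Deviations that genes share, or that affect a whole array, were not simulated, so the recovery below does not give the power in the real data. Of 100 genes shifted by a log2 of 1, 87, 88 and 88 were recovered at 6, 24 and 42 h (22183 genes each). In the double knockout comparison 88 were recovered, and between single genotypes 90 for Tlr9 knockout and 87 for Tlr7 knockout against WT and 84 between the knockouts (22761 genes each). In response differences from WT only 25 were recovered for the Tlr9 knockout and 11 for the Tlr7 knockout, and 48 for the double knockout (23167 genes each). A further 100 genes shifted by 2 were recovered in 97 to 100 cases at 6, 24 and 42 h and in 85, 85 and 96 cases in the response differences.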

Results

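Gene expression was measured in splenic B cells of the AM14 strain, whose B cells carry an antigen receptor that binds IgG as an autoantigen. The cells came from WT mice, mice lacking Tlr7, mice lacking Tlr9 and mice lacking both genes (the double knockout). Tlr7 encodes an endosomal receptor for single-stranded RNA, and Tlr9 encodes one for DNA. RNA was taken before stimulation (0 h) and after 6, 24 and 42 h with PL2-3, a monoclonal IgG against chromatin that reaches these B cells through their antigen receptor. The series addressed how TLR9 in autoreactive B cells affects responses that run through the antigen receptor and TLR7. Each of the 16 combinations of genotype and time was read on 1 array, which set the sample in Cy5 against a pool of unstimulated B cell RNA from all 4 genotypes in Cy3. With 1 array per genotype and time there were no replicates, and the number of arrays limits the precision. A limma p-value below therefore sets a difference against how far the genotypes, or the times, disagreed with each other.

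Between 37.4% and 62.7% of the spots stood well above background in the Cy5 channel. The Tlr9 knockout 0 h array was at the low end of this range, and the other 15 arrays lay between 40.9% and 62.7%. WT and Tlr7 knockout RNA lay on 1 slide, and Tlr9 knockout and double knockout RNA on the other. The presence of TLR9 and the slide therefore cannot be told apart, and only the comparisons of Tlr7 knockout with WT and of the double knockout with the Tlr9 knockout stay within a slide. No array held cells cultured without PL2-3, so PL2-3 and time in culture cannot be told apart.

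The knockouts were first examined at the level of their own transcripts. Tlr7 signal was lower in the cells that lack the gene, at -0.13 (SD 0.42, n = 8 arrays) against 1.12 (SD 0.47, n = 8 arrays) in the cells that have it, on the log2 scale relative to the pool. The difference of -1.25 had a 2-sided exact permutation p of 0.000466, and another bright Tlr7 probe gave -1.56 with an exact p of 0.000777. The remaining Tlr7 probe, above background on 4 arrays, gave 0.14 in the opposite direction (exact p = 0.0214). The Tlr9 probe gave -0.001 between cells without and with Tlr9 (exact p = 0.998), so it did not register the knockout. Under median centring of the arrays the Tlr9 probe gave -0.40, with an exact p of 0.0317. Cells with and without Tlr9 also lay on different slides. These exact tests treat the arrays as independent, although each side repeats the same genotypes over the times. Their p-values therefore describe these arrays and do not cover the spread between genotypes or mice.

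The first comparison asked how cells that keep at least 1 of the receptors had responded by 6 h. In WT, Tlr7 knockout and Tlr9 knockout cells, the chemokine genes Ccl4 and Ccl3 and genes of growth and ribosome production rose, and genes of mature B cell identity fell. Ccl4, a chemokine that attracts T cells and monocytes, rose by 7.94 ± 0.43 log2 units (SE, n = 3 genotypes, limma adjusted p = 8.68e-07), and the related chemokine Ccl3 rose by 4.08 ± 0.19. Myc, a transcription factor that drives cell growth, rose by 4.81 ± 0.23, and Egr2, an early target of antigen receptor signalling, by 5.23 ± 0.77. Il2ra, a chain of the interleukin-2 receptor, rose by 5.12 ± 0.51, Ahr, a ligand-activated transcription factor, by 4.96 ± 0.67, and Asns, which makes asparagine, by 4.62 ± 0.17 (Ahr and Asns were well above background on 2 of the 3 arrays at 0 h). Irf4, a transcription factor of activated B cells and plasma cells, rose and stood at 2.61 on the WT array, and the early activation marker Cd69 by 1.31 ± 0.14. Il2, a T cell growth factor, was not well above background at 0 h. It rose at least 9.3-fold in the Cy5 channel (2.94 in the log2 ratio). Here "at least" marks a gene that was not well above background in 1 of the compared groups. Its fold is a lower bound for the Cy5 channel alone, open to dye bias, and the ratio to the pool, which also carries the Cy3 channel, lay below it for each gene given this way.

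Among the genes that fell at 6 h, Itgb7, an integrin chain of homing lymphocytes, fell by 5.91 ± 0.16 (limma adjusted p = 3.61e-08). S1pr1, the receptor that lets lymphocytes leave lymphoid tissue, fell by 4.88 ± 0.24. The complement regulator Cd55 fell by 5.37 ± 0.30 and the immediate early gene Fos by 4.68 ± 0.12. Cd79a and Cd79b, the signalling chains of the B cell antigen receptor, fell by 3.45 ± 0.15 and 3.68 ± 0.14, and Ms4a1, which encodes CD20, fell by 2.84 ± 0.15. In all, 10538 of 22288 genes changed, 5157 higher and 5381 lower, and each gene named here for 6, 24 or 42 h moved the same way in all 3 genotypes. With median centring in place of loess, 75.7% of the called genes were higher, against 48.9% with loess, as that scaling moved the median of all genes by 0.23.

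Of 19 gene lists 10 passed the camera test at 6 h. The count of a list's members adjusted over the list alone is given where it differed from that over all genes. All 16 genes of the list of MYC targets and ribosome biogenesis rose, with a median of 2.54 (camera adjusted p = 1.71e-11, adjusted p = 0.103 with an estimated correlation). Srm, a MYC target that makes spermidine, rose by 3.12 ± 0.15, and Npm1, a nucleolar chaperone, by 2.67 ± 0.08. Of 22 genes of mature B cell identity 20 fell and 1 rose, with a median of -2.03 (adjusted p = 2.65e-09). This was the only list whose call held with an estimated correlation, at 6 h (adjusted p = 0.0489), at 24 h (0.0349) and at 42 h (0.0333). Of 20 genes of NF-κB signalling and activation 12 rose and 4 fell (adjusted p = 0.00975, adjusted p = 0.198 with an estimated correlation), among them Traf1 at 2.86 ± 0.19 and Tnfaip3, an inhibitor of the pathway, at 2.34 ± 0.15. Of 18 genes of the endoplasmic reticulum and secretion 12 rose and 2 fell (adjusted p = 0.00375, adjusted p = 0.419 with an estimated correlation). Of 16 genes of oxidative phosphorylation 8 rose and 1 fell (adjusted p = 0.00375, adjusted p = 0.353 with an estimated correlation).

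Interferon-stimulated genes moved down at 6 h. Of 20 such genes 13 fell and none rose, or 14 and 2 when adjusted over the list alone (adjusted p = 0.00375, adjusted p = 0.561 with an estimated correlation). Ddx58, which encodes the RNA sensor RIG-I, fell by 2.48 ± 0.14. Of 19 genes of the nucleic acid TLR pathway 11 fell and none rose (adjusted p = 0.00123, adjusted p = 0.156 with an estimated correlation). Markers of cells other than B cells fell as well. Of 15 myeloid markers 14 fell (adjusted p = 3.81e-06, adjusted p = 0.103 with an estimated correlation), with the complement gene C1qc at -2.63 ± 0.18. Of 10 markers of NK cells and plasmacytoid dendritic cells 7 fell, or 8 when adjusted over the list alone (adjusted p = 0.00283, adjusted p = 0.204 with an estimated correlation), with the granzyme gene Gzma at -3.60 ± 0.23. Of 10 erythroid markers 6 fell (adjusted p = 0.00375, adjusted p = 0.216 with an estimated correlation).

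The other 9 lists did not pass the camera test at 6 h. Members rose and fell in the lists of cell cycle genes (5 and 1 of 24), apoptosis and survival genes (8 and 6 of 19), immediate early genes of the antigen receptor (6 and 4 of 14) and glycolysis genes (5 and 1 of 14). The same held for the lists of class switching and T-bet (4 and 5 of 14, or 4 and 6 adjusted over the list alone), cytokines and chemokines (6 and 3 of 13, or 7 and 4), marginal zone and B1 cell genes (1 and 4 of 10, or 2 and 4), T cell markers (2 and 8 of 12, or 3 and 9) and plasma cell genes (5 and 3 of 14). Jchain, the joining chain of secreted antibody and a member of the plasma cell list, fell by 2.46 ± 0.37. Camera adjusted p for these lists ranged from 0.0789 for T cell markers to 0.794 for plasma cell genes. Fry did pass some of them: T cell markers (fry adjusted p = 9.43e-05), marginal zone and B1 genes (0.000651), cytokines and chemokines (0.00427) and glycolysis (0.0292). For the rest of the 9 lists fry adjusted p lay between 0.344 and 0.763. The 10 lists called by camera at 6 h also passed with fry (adjusted p at most 0.00842). The median, mean and camera test differed in sign in 1 to 6 of the 19 lists in each of the 10 comparisons. None of those lists passed the camera test.

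By 24 h, genes of DNA replication and cell division had joined those of growth. Uhrf1, which maintains DNA methylation in dividing cells, rose by 4.44 ± 0.35 (limma adjusted p = 8.79e-06), and Mcm6 and Mcm3, subunits of the replicative helicase, rose by 3.59 ± 0.21 and 2.67 ± 0.22. Uck2, which salvages pyrimidines, rose by 4.37 ± 0.09 and the tubulin gene Tubb6 by 4.48 ± 0.20. Pdcd1, the inhibitory receptor PD-1, rose by 4.52 ± 0.46 (like Tubb6 and Bcl2l11, it was well above background on 2 of the 3 arrays at 0 h), and Ccl4 remained 7.22 ± 0.43 above 0 h. Il6, an inflammatory cytokine, rose at least 6.01-fold in the Cy5 channel (2.52 in the log2 ratio), and Bcl2l11, a gene that promotes apoptosis, rose by 2.08 ± 0.16. Bcl6, the transcription factor of germinal centre B cells, fell by 3.45 ± 0.20, Klf2, a factor of resting lymphocytes, by 4.75 ± 0.29, the complement receptor gene Cr2 by 4.64 ± 0.47 and S1pr1 by 4.75 ± 0.24. Cd69 and the costimulatory gene Cd86 stood below their 0 h level, at -0.95 ± 0.14 and -1.83 ± 0.40, and the Tlr9 probe, which did not register the knockout, was at -0.89 ± 0.13 over these genotypes and at -0.74 without the Tlr9 knockout arrays.

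At 24 h 10952 of 22288 genes changed, 5106 higher and 5846 lower. Of 24 cell cycle genes 23 rose, or 24 when adjusted over the list alone, with a median of 2.45 (camera adjusted p = 5.49e-09, adjusted p = 0.284 with an estimated correlation). Of 14 glycolysis genes 9 rose and 1 fell (adjusted p = 0.00396, adjusted p = 0.505 with an estimated correlation). Hk2, the hexokinase of growing cells, was 3.31 ± 0.16 above 0 h, where 2 of 3 arrays were well above background for it. All 16 MYC and ribosome genes rose again (adjusted p = 2.51e-10, adjusted p = 0.116 with an estimated correlation), as did 14 of 16 genes of oxidative phosphorylation (adjusted p = 1.78e-05, adjusted p = 0.165 with an estimated correlation). Of 22 genes of mature B cell identity 20 fell, or 21 when adjusted over the list alone (adjusted p = 2.51e-10). Of 18 endoplasmic reticulum genes 10 rose (adjusted p = 0.00492, adjusted p = 0.426 with an estimated correlation), and of 19 genes of the nucleic acid TLR pathway 13 fell and 1 rose (adjusted p = 0.000744, adjusted p = 0.116 with an estimated correlation). All 10 erythroid, 14 of 15 myeloid and 9 of 10 NK and plasmacytoid markers fell (adjusted p at most 7.74e-05, each with adjusted p = 0.116 with an estimated correlation). The interferon-stimulated list did not pass (adjusted p = 0.644). Its member Ifih1, the RNA sensor MDA5, rose by 3.52 ± 0.46, while Rsad2, an antiviral enzyme, fell by 2.06 ± 0.21 (well above background on 2 of 3 arrays at 24 h). With median centring, 77.0% of the called genes were higher, against 46.6% with loess.

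At 42 h genes of cell division and glycolysis stood high. Rrm2, which supplies nucleotides for replication, rose by 3.98 ± 0.56 (limma adjusted p = 0.00047), and Birc5, which encodes the mitotic protein survivin, rose by 3.80 ± 0.74. Without the Tlr9 knockout arrays Rrm2 was at 4.79 and Birc5 at 4.69. Scd2, a fatty acid desaturase, rose and stood at 4.91 in WT, 4.87 in the Tlr7 knockout and 2.44 in the Tlr9 knockout. The metallothionein Mt1 rose by 3.90 ± 0.28 and the glycolytic enzyme gene Gapdh by 2.54 ± 0.32. Ccl4 and Ccl3 were still up by 4.90 ± 0.43 and 3.97 ± 0.19, Myc by 2.23 ± 0.23, and Il6 was at least 3.02-fold higher in the Cy5 channel (1.44 in the log2 ratio). Xbp1, a transcription factor of antibody secretion, rose by 0.52 ± 0.14. Cr2 fell by 4.43 ± 0.47, Bcl6 by 3.06 ± 0.20 and Fos by 4.78 ± 0.12, although Fos was well above background on only 1 of the 3 arrays at 42 h. The globin gene Hbb-bs fell by 4.36 ± 0.55 and Gzma by 4.36 ± 0.23. The globin gene Hba-a1 and the adhesion gene Vcam1 fell as well, to -4.33 and -3.43 on the WT array (Vcam1 was well above background on 2 of the 3 arrays at 42 h).

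Of 22288 genes 8544 changed at 42 h, 3897 higher and 4647 lower. All 24 cell cycle genes rose, with a median of 2.50 (camera adjusted p = 8.97e-11, adjusted p = 0.236 with an estimated correlation), and 12 of 14 glycolysis genes rose and 1 fell (adjusted p = 2.16e-05, adjusted p = 0.295 with an estimated correlation). Of 16 MYC and ribosome genes 15 rose (adjusted p = 1.36e-09, adjusted p = 0.111 with an estimated correlation). Of 22 genes of mature B cell identity 18 fell, or 19 when adjusted over the list alone (adjusted p = 9.26e-11). Genes of oxidative phosphorylation (14 of 16 higher, or 15 adjusted over the list alone, adjusted p = 1.14e-06, adjusted p = 0.111 with an estimated correlation) and of the endoplasmic reticulum (10 of 18 higher and 1 lower, or 11 and 1, adjusted p = 0.000553, adjusted p = 0.295 with an estimated correlation) rose. The nucleic acid TLR pathway (13 of 19 lower, adjusted p = 0.000647), erythroid markers (7 of 10 lower, or 9 adjusted over the list alone, adjusted p = 4.26e-05) and NK and plasmacytoid markers (8 of 10 lower, or 9, adjusted p = 1.69e-05) fell, each with adjusted p = 0.111 with an estimated correlation. Of 12 T cell markers 5 fell and 1 rose (adjusted p = 0.0348, adjusted p = 0.119 with an estimated correlation), 12 of 15 myeloid markers fell (adjusted p = 1.73e-06, adjusted p = 0.109 with an estimated correlation), and plasma cell genes did not pass (4 higher and 1 lower of 14, adjusted p = 0.214). With median centring, 58.6% of the called genes were higher, against 45.6% with loess. The Tlr9 knockout moved the median of the cell cycle list in another order over time than the other genotypes (given below for single arrays). Without its arrays 11683 genes changed at 6 h, 11810 at 24 h and 9901 at 42 h.

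The next comparison asked what changed in cells without either receptor, first as the number of genes at least 2-fold from the genotype's own 0 h array. As no array held cells cultured without PL2-3, these changes cannot be told apart from those of time in culture. The double knockout still changed, with 3902 such genes at 6 h. The counts at 6 h were 4713 in WT, 4784 in the Tlr7 knockout and 4486 in the Tlr9 knockout. At 24 h the double knockout had 1864 such genes and the others had 4466, 4446 and 4767 in the same order. At 42 h the counts were 2705 in the double knockout, 2926 in WT, 3510 in the Tlr7 knockout and 3154 in the Tlr9 knockout. Each count also rests on the genotype's single 0 h array. The SD of the log2 ratios to the pool, which does not, was 0.635, 0.447 and 0.532 in the double knockout at 6, 24 and 42 h. It was 0.685, 0.630 and 0.526 in WT, 0.704, 0.629 and 0.583 in the Tlr7 knockout and 0.625, 0.648 and 0.494 in the Tlr9 knockout. By this measure the double knockout lay below all others at 24 h only. The median of the MYC and ribosome list in the double knockout was 2.20 at 6 h and 1.15 at 42 h, against 2.67 and 1.25 in WT, and at 24 h it lay well below the 2.19 of WT. The mature B cell identity list of the double knockout stood at -1.97, -1.42 and -1.85. The cytokine and chemokine list of the double knockout had medians of -0.07, -0.16 and -0.03, with members that moved both ways, such as Ccl4 at 6.29, 2.71 and 3.91 and Lta at -1.96, -2.60 and -3.44. Its medians lay at percentiles 37.1, 13.2 and 47.1 of 10000 random lists (0.05 at 6 h and 0.11 at 42 h with median centring). Single arrays carry no p-value, and these counts were larger with the deposited log ratios (4152 in the double knockout at 24 h and 7744 in WT).

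**Figure D1:**
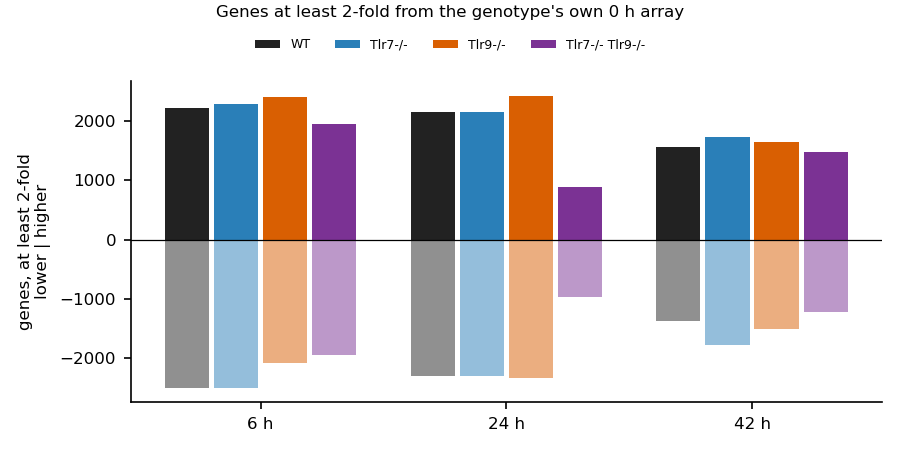
Number of genes at least 2-fold higher (upper bars) or lower (paler lower bars) than on the 0 h array of the same genotype, at 6, 24 and 42 h with PL2-3 (1 array each). The double knockout had 1864 genes at 24 h, and the other genotypes had between 4446 and 4767.

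Over the 3 stimulated times together, the double knockout was lower than the other genotypes in Ccl4 and Lta, without passing the test across all genes. Ccl4 was at -2.48 ± 0.57, Lta, which encodes lymphotoxin alpha, at -2.16 ± 0.45, Batf, a transcription factor of activated lymphocytes, at -1.60 ± 0.38 and Il6 at -1.54 ± 0.37 (well above background on 2 of 3 double knockout and 8 of 9 other arrays), while Cd5, a dampener of antigen receptor signalling, was at 1.44 ± 0.32 (limma adjusted p = 0.119 for each). With limma, 0 of 22823 genes passed and 4382 had an unadjusted p under 0.05. Without the Tlr9 knockout arrays 2961 genes passed, and without the Tlr9 knockout 42 h or 6 h array alone 1161 and 530 did. Without any Tlr9 knockout array, the double knockout on 1 slide met WT and Tlr7 knockout cells on the other. Genotype and slide cannot be told apart in that fit. In it Lta was at -2.49 (limma adjusted p = 4.97e-05), Il6 at -1.85 (0.00226), Batf at -1.89 (0.00655), Ccl4 at -2.63 (0.0218) and Cd5 at 1.72 (9.15e-05). Within slide 2 the double knockout met only the Tlr9 knockout, with 3 arrays of each. There 3 genes passed and none of these 5. Lta was at -1.51, Il6 at -0.91, Batf at -1.03, Ccl4 at -2.17 and Cd5 at 0.89 (limma adjusted p = 0.942 for each). With so few arrays, this does not show that the 5 genes were alike within the slide.

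The list tests of this comparison gave 10 calls, none of which held with an estimated correlation. The MYC and ribosome list (median -0.41, camera adjusted p = 6.72e-07, adjusted p = 0.422 with an estimated correlation) and oxidative phosphorylation (-0.25, adjusted p = 6.72e-07, adjusted p = 0.397 with an estimated correlation) were lower in the double knockout. So were cytokines and chemokines (-0.67, adjusted p = 0.000218, adjusted p = 0.397 with an estimated correlation), glycolysis (-0.67, adjusted p = 0.000546, adjusted p = 0.457 with an estimated correlation) and cell cycle (-0.55, adjusted p = 0.000644, adjusted p = 0.54 with an estimated correlation). Endoplasmic reticulum genes were lower too (-0.24, adjusted p = 0.00126, adjusted p = 0.441 with an estimated correlation). Interferon-stimulated genes were higher (0.57, adjusted p = 1.02e-05, adjusted p = 0.441 with an estimated correlation), as were marginal zone and B1 genes (0.56, adjusted p = 0.00397, adjusted p = 0.397 with an estimated correlation). Mature B cell identity (0.34, adjusted p = 0.000243, adjusted p = 0.441 with an estimated correlation) and the nucleic acid TLR pathway (0.22, adjusted p = 0.00241, adjusted p = 0.422 with an estimated correlation) were higher with loess, but their medians were -0.04 and -0.14 with median centring, which moved the median of all genes by -0.14. No member of any list passed over all genes. Adjusted over the list alone, the called lists had 11 MYC and ribosome genes, 7 oxidative phosphorylation genes, 6 cytokine genes, 1 endoplasmic reticulum gene and 1 glycolysis gene lower, and 4 mature B cell genes, 2 interferon-stimulated genes, 1 cytokine gene and 1 marginal zone and B1 gene higher.

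**Figure D2:**
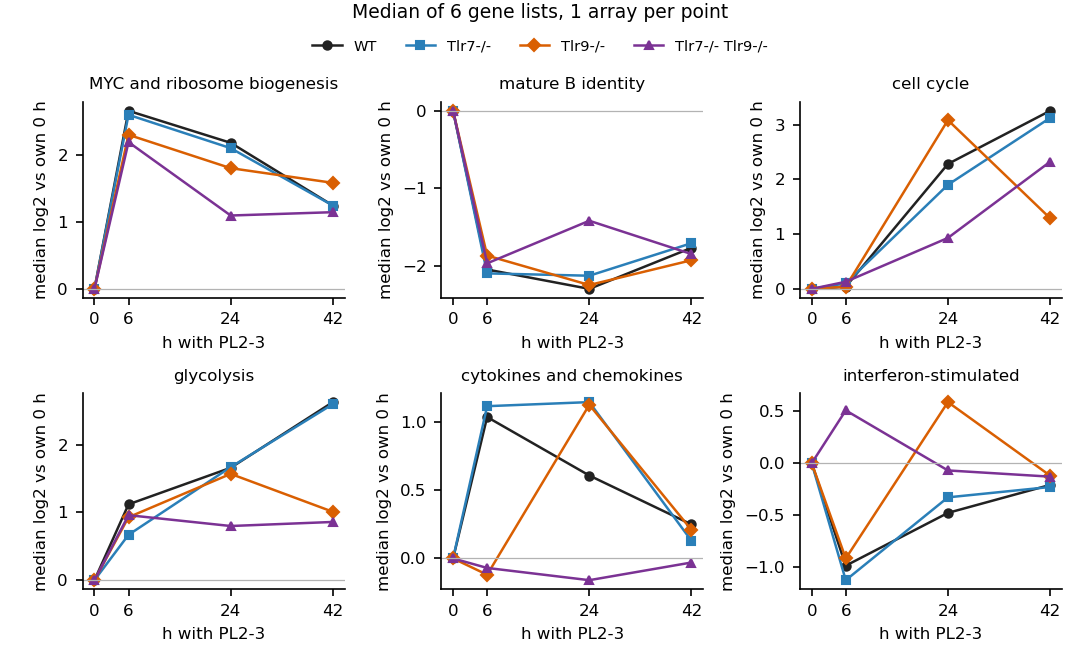
Median log2 difference from the own 0 h array for 6 gene lists (vertical axes) against hours with PL2-3, 1 line per genotype and 1 array per point. Cell cycle genes of the Tlr9 knockout stood at 3.08 at 24 h and 1.29 at 42 h, and those of WT at 2.28 and 3.25.

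Loss of Tlr7 alone was compared with WT within 1 slide. Between stimulated Tlr7 knockout cells and WT 1 gene passed the threshold. Arl2bp, which encodes a partner of the small GTPase ARL2, was at -2.70 ± 0.09 (limma adjusted p = 4.79e-06, lower at all 3 times), and 412 of 22823 genes had an unadjusted p under 0.05. Arl2bp was as low at 0 h, at -2.14 in the Tlr7 knockout against 0.69 in WT, and it stood at -0.31 in the double knockout. Tlr7 itself was at -1.31 ± 0.22 (adjusted p = 0.501 over all genes, and 0.0283 on slide 1 alone, where 3 genes passed). As the deleted gene did not pass in the main fit, the count past the threshold does not give how many genes differed. Of 19 lists, myeloid markers were lower (median -0.26, camera adjusted p = 3.17e-05, adjusted p = 0.784 with an estimated correlation), with a median of 0.09 in the deposited log ratios. Markers of NK and plasmacytoid cells were lower as well (-0.13, adjusted p = 0.0473, adjusted p = 0.975 with an estimated correlation). No member of either list passed over all genes or adjusted over the list alone. The arrays of these genotypes correlated across genes at 0.978 at 6 h, 0.981 at 24 h and 0.933 at 42 h, where genes are not independent replicates.

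Loss of Tlr9 was compared with WT and with loss of Tlr7 across the slides. The clearest differences were in genes that report sex. Eif2s3y and Ddx3y, both on the Y chromosome, were at least 37.3-fold and 16.5-fold higher in the Cy5 channel (4.83 and 3.82 in the log2 ratio) in stimulated Tlr9 knockout cells than in WT (limma adjusted p = 2.18e-05 and 1.93e-05). Xist, which silences an X chromosome in female cells, was at least 10.8-fold lower (-3.25 in the log2 ratio, adjusted p = 2.18e-05). The pattern was the same at 0 h, with Ddx3y at 1.58 on the Tlr9 knockout array and between -2.98 and -2.76 on the other 3. Eif2s3y and Ddx3y were well above background on the 4 Tlr9 knockout arrays and no others, and Xist on the other 12. What these genes report therefore cannot be told apart from the Tlr9 knockout in any comparison with it, that with the double knockout included. Slc7a4, an orphan member of an amino acid carrier family, was at least 13.9-fold higher (3.16 in the log2 ratio). Other named genes past the threshold were Irs2 at 0.96 ± 0.12 and Mfap1a at 0.79 ± 0.09, and, lower, Itln1 at -1.56 ± 0.20, Slc7a3 at -1.42 ± 0.16, Marchf3 at -1.40 ± 0.14 and Niban2 at -0.96 ± 0.11. In all, 13 of 22823 genes passed, 6 higher and 7 lower, and 2120 had an unadjusted p under 0.05. Marginal zone and B1 genes were the only list called (median 0.34, camera adjusted p = 0.0106, adjusted p = 0.26 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone.

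Against the Tlr7 knockout, 29 genes passed in the Tlr9 knockout, 12 higher and 17 lower, and 2059 had an unadjusted p under 0.05. Tlr7 was higher at 1.68 ± 0.22 (limma adjusted p = 0.026) and Arl2bp at 2.65 ± 0.09. Lower were Wfdc21 at -4.54 ± 0.58, the lymphocyte receptor Cd6 at -1.67 ± 0.16 and Erdr1 at -1.24 ± 0.13. Tfe3, a transcription factor of lysosomal genes, was higher at 0.88 ± 0.11 and the centrosomal gene Cep63 at 0.82 ± 0.10. With the own 0 h array subtracted Cep63 was at -0.18, so it already differed at 0 h. The genes that report sex, and the slide, set these genotypes apart too, so none of these differences can be assigned to the loss of Tlr9. Marginal zone and B1 genes were again the only list called (median 0.22, camera adjusted p = 0.0418, adjusted p = 0.422 with an estimated correlation), and this median was -0.02 with median centring. Their members did not pass over all genes or adjusted over the list alone. Without the Tlr9 knockout 24 h array these counts were 74 genes against WT and 81 against the Tlr7 knockout. Leaving out any 1 of the other 8 arrays of WT, the Tlr7 knockout or the Tlr9 knockout gave 6 or 7 genes against WT. Against the Tlr7 knockout 8 genes passed without its 24 h array, 12 without its 6 h array, 14 without its 42 h array, and 15 and 17 without the Tlr9 knockout 6 h and 42 h arrays.

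On single arrays several cytokine genes of the Tlr9 knockout stood lower than those of WT at 6 h. Tnf, an inflammatory cytokine, stood at 0.65 at 6 h in the Tlr9 knockout against 2.58 in WT and 2.35 in the Tlr7 knockout, and at 2.08 against 1.90 and 1.82 at 24 h. Il6 stood at 0.29 at 6 h, 2.39 at 24 h and 0.46 at 42 h in the Tlr9 knockout, and at 1.16, 2.52 and 1.89 in WT, but it was not well above background on the Tlr9 knockout 6 h array, so that value is not an exact level. In the double knockout Il6, not well above background at 24 h, did not exceed 0.19 and Tnf did not exceed 0.17 at any stimulated time. Ebi3, a subunit of interleukins 27 and 35, stood at -0.17 at 6 h in the Tlr9 knockout and at 2.13 in WT. The median of the cytokine list against the own 0 h array was -0.12 at 6 h and 1.13 at 24 h in the Tlr9 knockout, at percentiles 22.2 and 100 of random lists, and 1.04 and 0.61 in WT. Under median centring the Tlr9 knockout value at 6 h was 0.20. Interferon-stimulated genes of the Tlr9 knockout had a median of -0.92 at 6 h and 0.59 at 24 h, while those of the double knockout were at 0.51 at 6 h, where all 20 lay above the Tlr9 knockout.

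The median of the cell cycle list was highest at 24 h in the Tlr9 knockout and at 42 h in the other genotypes, though not each member followed it. Mki67, a marker of dividing cells, stood at 1.13 at 42 h in the Tlr9 knockout, at -2.87 from its 24 h value. At 24 h and 42 h it stood at 2.11 and 4.54 in WT, at 2.06 and 4.52 in the Tlr7 knockout and at 0.59 and 3.41 in the double knockout. The Tlr9 knockout's cell cycle list lay 1.73 below WT in the median at 42 h, with 22 of 24 genes lower, and at 24 h it lay 0.60 above WT with loess and at -0.23 with median centring. Egr2 and Csf1, a growth factor of macrophages, stood at 5.74 and 2.89 in the Tlr9 knockout at 42 h against 1.58 and -0.36 in WT. Across genes, the Tlr9 knockout correlated with WT at 0.943 at 6 h, 0.932 at 24 h and 0.719 at 42 h, and the double knockout at 0.935, 0.821 and 0.751. Mki67, Tnf, Ebi3, Csf1 and Egr2 were chosen for this account after their values were seen.

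**Figure D3:**
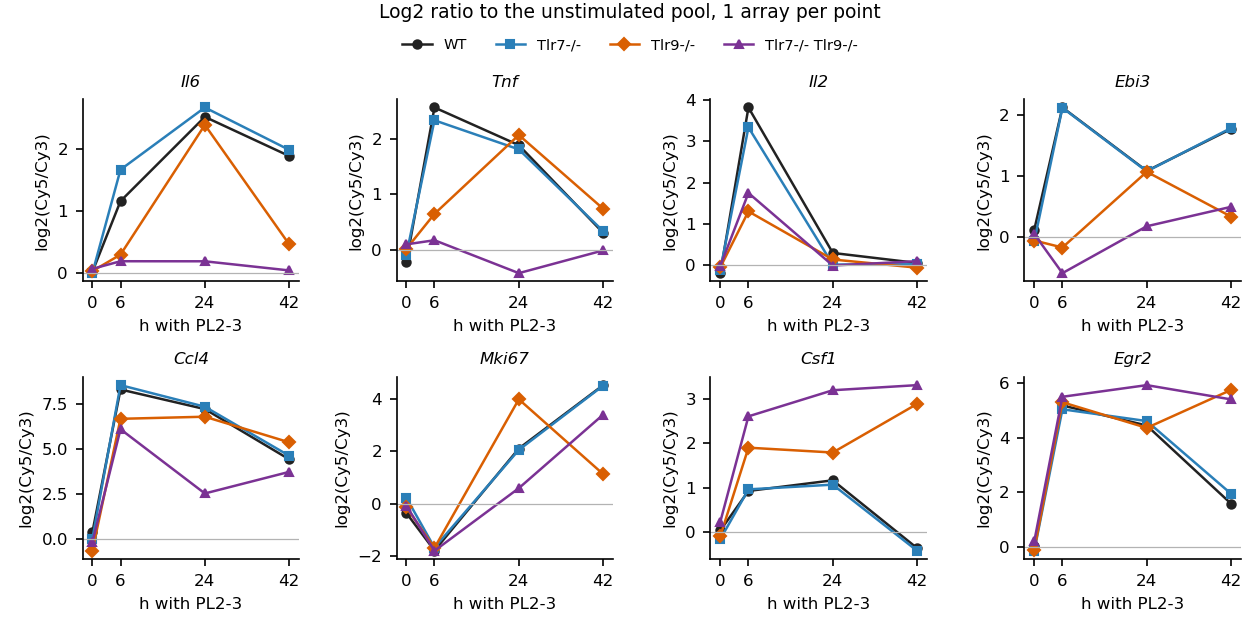
Log2 ratio of each sample to the unstimulated pool (vertical axes) for 8 genes against hours with PL2-3, 1 line per genotype and 1 array per point. Il6 stayed at or below 0.19 in the double knockout and reached between 2.39 and 2.68 at 24 h in the other genotypes.

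The last comparisons asked whether the response itself, each genotype's stimulated arrays less its 0 h array, differed between genotypes. Their p-values rest on the spread of the stimulated arrays and do not measure the error of a single 0 h array. The Tlr9 knockout response differed from that of WT in 309 of 23252 genes, 258 higher and 51 lower, and 2133 had an unadjusted p under 0.05. Named genes were Anapc1, a subunit of the anaphase-promoting complex, at -3.34 ± 0.24 (limma adjusted p = 0.0051), the mitochondrial ribosomal gene Mrps9 at -1.60 ± 0.20, the potassium channel gene Kcna7 at 1.75 ± 0.32 and the carbonyl reductase gene Cbr1 at 1.63 ± 0.23. These differences lay in 1 array at 0 h each: Anapc1 was at 3.33, Mrps9 at 1.48 and Kcna7 at -1.20 on the Tlr9 knockout 0 h array, and Cbr1 at 1.32 on the WT 0 h array. The count fell to 1 when any WT or Tlr7 knockout stimulated array, or the Tlr9 knockout 6 h array, was left out, and to 0 with the deposited log ratios or median centring (2468 and 976 genes at an unadjusted p under 0.05, limma). It was 121 without the Tlr9 knockout 42 h array and 174 and 187 without the double knockout 6 h and 42 h arrays. No list passed.

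The Tlr7 knockout response passed the threshold against WT in 0 of 23291 genes with limma, with 473 at an unadjusted p under 0.05. Its lists of myeloid markers (median -0.41, camera adjusted p = 0.000728), erythroid markers (-0.35, adjusted p = 0.00975) and plasma cell genes (-0.20, adjusted p = 0.0464) were lower, with adjusted p = 0.694, 0.694 and 0.725 with an estimated correlation and no member past the threshold over all genes or adjusted over the list alone. The double knockout response differed from the mean of the others in 9 of 23230 genes, 3 higher and 6 lower, and 1876 had an unadjusted p under 0.05. Orai2, a calcium channel subunit, was at 4.19 ± 0.29 (limma adjusted p = 0.00173) and the palmitoyltransferase gene Zdhhc4 at 1.96 ± 0.14, with 0 h values of -3.04 and -1.85 in the double knockout. Zdhhc4 was not well above background on that 0 h array, so its value is not an exact difference. Npepps, an aminopeptidase, was at -2.66 ± 0.23 and the erythroid gene Hemgn at -2.19 ± 0.25, with 0 h values of 2.71 and 3.27. Of 19 lists 12 were called, 6 higher and 6 lower, with adjusted p between 0.559 and 0.688 with an estimated correlation. No member of these lists passed over all genes or adjusted over the list alone. The count was 5 without the WT 24 h array, any stimulated Tlr7 knockout array, the Tlr9 knockout 6 h or 42 h array or the double knockout 42 h array, each left out alone.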

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

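The tests of the array order, of red cell genes, of the quality of the Tlr9 knockout 42 h array and of the Tlr9 knockout 0 h array in this part were chosen after the results were seen.

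In WT, the Tlr7 knockout and the double knockout, 83 genes were at least 2-fold higher at 42 h than at 24 h, and all 83 moved the opposite way in the Tlr9 knockout, where the cell division gene Mki67 changed by -2.87 against 2.43, 2.46 and 2.82 in the others. A faulty 42 h array stays open, since the 53.0% of its spots well above background in Cy5 lay between the 40.9% and 62.7% of the other 42 h arrays, a range that holds 15 of the 16 arrays and so decides nothing. An exchange of the 24 h and 42 h samples stays open too: with cell cycle and histone genes left out, exchanging the labels raised the summed correlation with each other genotype, by at least 0.053 over 23047 genes, while among the other genotypes the same exchange in 1 of a pair gave between -0.202 and -0.047, but an exchange needs both arrays out of place, and while the 42 h array alone gave 0.135 with WT, 0.111 with the Tlr7 knockout and 0.023 with the double knockout, the 24 h array alone gave -0.081, -0.032 and 0.069 in the same order. Red cell genes picked after their values were seen also ran against the others, with Hbb-bs at 1.74 (others -1.56 to -0.82), Hba-a1 at 1.28 (-0.77 to -0.03) and Alas2 at 0.97 (-0.79 to -0.41). A response that ends earlier in Tlr9 knockout cells still cannot be told apart from an exchange, because the list of 10 erythroid markers changed by 0.42 in the Tlr9 knockout and by 0.26, 0.01 and -0.01 in the others, and a loss of B cells would raise the share of such RNA as well.

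The Tlr9 knockout response differed from the WT response in 309 genes by a test of the difference itself. Of these, 308 genes (99.7%) differed more between the genotypes at 0 h than when stimulated, with a median absolute difference of 1.17 at 0 h and 0.08 when stimulated, and in 294 of the 309 the Tlr9 knockout 0 h array lay outside the other 3. That array had 37.4% of its spots well above background in Cy5, and the other 15 arrays had at least 40.9%. Its log2 ratios had an SD of 0.279 over probes, against 0.184 in WT, 0.153 in the Tlr7 knockout and 0.166 in the double knockout at 0 h. The test takes its spread from the stimulated arrays and assumes that each 0 h array varies like them, so its p-values do not measure error at 0 h. As only 1 of the 309 genes passed in the stimulated comparison, the way they were called fixes most of that share, and it does not show that the array is the cause. A fault of the array and a difference that unstimulated Tlr9 knockout cells carry cannot be told apart, with 1 array at 0 h for each genotype.

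Among the named genes of that comparison, Anapc1 was at -3.34, Mrps9 at -1.60, Kcna7 at 1.75 and Cbr1 at 1.63. The double knockout response differed from the mean of the others in 9 genes, again by a test of the difference, with Orai2 at 4.19, Zdhhc4 at 1.96, Npepps at -2.66, Hemgn at -2.19 and Vmn2r42 at -1.20. Orai2 (-3.04), Zdhhc4 (-1.85), Npepps (2.71) and Hemgn (3.27) had double knockout 0 h values apart from the other 3 genotypes, whereas for Vmn2r42 the 0 h values that stood apart were those of WT (-1.62) and the Tlr9 knockout (-0.96). Zdhhc4 was not well above background on the double knockout 0 h array, and Vmn2r42 was above it on the WT and Tlr9 knockout 0 h arrays alone, so these values are not exact differences.

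Cd69 and Rrm2 moved one way at 6 h and the other way later, and the difference between the times was not tested. Cd69 was at 1.31 at 6 h, -0.95 at 24 h and -0.85 at 42 h in the mean of WT, Tlr7 knockout and Tlr9 knockout. Rrm2 was at -1.07 at 6 h, 4.07 at 24 h and 3.98 at 42 h in the same genotypes.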

How the results depend on the processing

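The exchange of the Tlr9 knockout 24 h and 42 h labels, the fits without Tlr9 knockout arrays and the fits within 1 slide were chosen after the results were seen. Where no construction is named, the cause was not tested. Of the alternative counts and knockout probe values 226 stayed the same, 112 moved and 1 became stronger. Of the values of single genes and lists 2661 stayed, 276 became weaker, 21 stronger and 6 reversed. Of the 60 list calls, 57 were lost with an estimated correlation and all 60 held with the mean over probes. Named genes kept their direction and call in all 779 alternatives at 6 h, 605 of 610 at 24 h and 525 of 530 at 42 h. For Tlr9 knockout against WT it was 187 of 270, against Tlr7 knockout 134 of 189, for the Tlr9 knockout response 66 of 108 and for the double knockout response 90 of 123. What depth limits here is dim probes: no filter or a stricter filter on signal over background moved the count of Tlr9 knockout response differences from 309 to 1360 or to 1.

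The responses to PL2-3 moved past 1.5 times only with a minimum of 2-fold, which passes fewer genes by construction: 4364 genes at 6 h, 4249 at 24 h and 2650 at 42 h. Leaving out 1 array gave 8837 to 11395, 9370 to 11861 and 6528 to 8768 genes. Without Tlr9 knockout arrays the counts were 11683, 11810 and 9901, with its labels exchanged 10451, 10001 and 9365, and with all 16 arrays 11309, 11097 and 9460. Array weights gave 12525, 12920 and 9655, and probes above background on every array 8535, 8787 and 7469. Median centring gave 10527 genes at 6 h (75.7% higher against 48.9%), 10235 at 24 h (77.0% against 46.6%) and 6498 at 42 h (58.6% against 45.6%), and it set the median of all genes to 0.229 at 6 h and 0.231 at 24 h.

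For the double knockout against the others, limma passed 0 genes (4382 at an unadjusted p under 0.05), and the count was 1 with the mean over probes, 1 with the labels exchanged, 7 with the slide as a block, 3 on slide 2 alone, 2961 without Tlr9 knockout arrays, and 0 to 1161 with 1 array left out, the highest without the Tlr9 knockout 42 h array. The fit without Tlr9 knockout arrays also set slide 2 against slide 1. With the slide as a block, as on slide 2 alone, the double knockout was compared with the Tlr9 knockout only, which is another comparison. Median centring set the median of all genes to -0.139. With the own 0 h array subtracted the count was 778. That setting passed 3271 genes for Tlr9 knockout against WT, 236 for Tlr7 knockout against WT and 2705 for Tlr9 against Tlr7 knockout. By construction it adds the noise of 1 array to 3 differences alike, which the fit cannot see, and it removes what already differed at 0 h. Under it alone, Eif2s3y (-0.32), Ddx3y (-0.62) and Niban2 (0.21) reversed for Tlr9 knockout against WT, Arl2bp (0.13) and Tlr7 (0.37) for Tlr7 knockout against WT, and Cep63 (-0.18) for Tlr9 against Tlr7 knockout.

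For Tlr9 knockout against WT (13 genes, 46.2% higher) the count was 5 with the deposited log ratios and 5 with the series table (60% higher in both), 37 with median centring (10.8% higher, median of all genes -0.28), 460 with array weights, 20 with the labels exchanged, 8 without a time term, and 6 to 74 with 1 array left out, the highest without the Tlr9 knockout 24 h array. With scale normalization it was 14 (57.1% higher). For Tlr9 against Tlr7 knockout (29 genes, 41.4% higher) it was 12 with the log ratios and 12 with the series table, 913 with array weights, 13 without a time term, 40 with median centring (12.5% higher, median of all genes -0.27) and 8 to 81 with 1 array left out. For Tlr7 knockout against WT (1 gene) it was 4 with eBayes trend and robust, 8 with array weights, 3 on slide 1 alone and 1 to 2 with 1 array left out, the highest without the Tlr7 knockout 42 h array.

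For the Tlr9 knockout response (309 genes, 83.5% higher) the count was 173 without background correction, 0 with the log ratios, 0 with the series table and 0 with median centring (limma, 2468, 2630 and 976 at an unadjusted p under 0.05), 2518 with scale normalization (69.9% higher), 1360 without a filter, 1 with probes above background on every array, 575 with trend and robust, 843 with array weights and 1 to 305 with 1 array left out. For the Tlr7 knockout response (0 genes with limma, 473 at an unadjusted p under 0.05) it was 76 with scale normalization (11.8% higher), 5 without a filter, 10 with trend and robust, 19 with array weights and 0 with any 1 array left out. For the double knockout response (9 genes, 33.3% higher) it was 864 with scale normalization, 1 with median centring (higher) and 5 to 8 with 1 array left out. Median centring set the median of all genes to -0.117 for the Tlr9 knockout response and 0.121 for the Tlr7 knockout response.

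With an estimated correlation the number of lists called dropped from 10 to 1 at 6 h, from 10 to 1 at 24 h and from 11 to 1 at 42 h. It dropped to 0 from 10 for the double knockout, from 1 for Tlr9 knockout against WT (2 with the mean over probes), from 2 for Tlr7 knockout against WT, from 1 for Tlr9 against Tlr7 knockout, from 3 for the Tlr7 knockout response and from 12 for the double knockout response. Genes at least 2-fold from the own 0 h array at 6, 24 and 42 h were, with a log2 minimum of 1.5, 2506, 2120 and 1328 in WT, 2589, 2116 and 1635 in the Tlr7 knockout, 2183, 2234 and 1159 in the Tlr9 knockout and 1912, 684 and 1182 in the double knockout. With the deposited log ratios they were 8034, 7744 and 6223, then 7836, 7504 and 6757, then 7359, 8138 and 6076, then 6665, 4152 and 5306 in the same order. The Tlr9 probe moved to 0.057 with the log ratios and to -0.40 with median centring (exact p = 0.0317). Aquantile normalization leaves the log ratios as they are and so moved nothing.

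Each genotype and time has 1 array, so no replicate numbers pair the arrays. Genotype or time entered the fits as a term instead. This matched the arrays within each genotype for the responses and within each time for the genotype comparisons. The slide as a block was not run for the responses to PL2-3, where it is nested in genotype, nor for the comparisons of single genotypes and the response differences, where the slide is shared or coincides with genotype. Response differences were not run without a 0 h array they rest on.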

Other observations

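The test of a slide offset, the gene neighbourhood counts and the genes chosen from single arrays in this part were chosen after the results were seen. The counts of other splits were planned.

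Some single genes stood apart at 6 h between genotypes with and without TLR9, without a test of the difference, and the list of NF-κB signalling and activation did not pass between Tlr9 knockout and WT (camera adjusted p = 0.709). Il2 stood at 3.82 in WT and 3.34 in the Tlr7 knockout, and at 1.30 in the Tlr9 knockout and 1.75 in the double knockout. Lta stood at 0.98 and 0.66 against -1.58 and -1.79, and Batf at 3.82 and 4.09 against 2.33 and 1.77. Cd86, a ligand that costimulates T cells, ran the other way, with -0.28 and -0.40 against 1.02 and 1.62, as did Cd5 with 0.33 and 0.44 against 1.90 and 2.09. Isg15, an interferon-induced ubiquitin-like protein, stood at 0.95, 1.03 and 1.08 in WT, the Tlr7 knockout and the double knockout at 6 h and at -0.74 in the Tlr9 knockout, and Ifi44 at 2.52 in the double knockout and between -0.94 and -0.49 in the others.

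The cytokine and chemokine list was lower at 6 h on the single arrays of the genotypes without TLR9, which share a slide. This was not tested at 6 h, and over the stimulated times the list was not called by camera between Tlr9 knockout and WT. The median difference between the slides was -0.88 over 13 genes at 6 h, with 10 of them lower. The same difference was 0.02 at 0 h, -0.29 at 24 h and -0.33 at 42 h. The 0 h value cannot decide on a constant offset between the slides, as loess had already centred each array. Members such as Il2 and Il6 were also not well above background on any 0 h array, so an offset might not show there. That TLR9 may be needed for the full early cytokine response to PL2-3 is a hypothesis found and examined on the same arrays. A difference between the slides in how stimulated samples were cultured or labelled stays open, untested.

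Arl2bp stood at -2.14 or lower on all 4 Tlr7 knockout arrays and at -0.31 or higher on the other 12. Slc7a4 stood between 0.98 and 2.55 on the Tlr9 knockout arrays and at -0.98 or lower on the others. Among 44 genes within 10 Mb of Tlr7 on the reference, 4 (9.1%) had an unadjusted p under 0.05 between Tlr7 knockout and WT, against 1.8% of the other genes (Fisher's exact p = 0.00804). Near Tlr9 it was 25 of 212 genes (11.8%) between Tlr9 knockout and WT, against 9.3% (Fisher's exact p = 0.233). Fisher's test treats the genes as independent, and its result near Tlr9 does not show that no gene there differed.

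Other splits of the arrays were counted for each comparison of groups. Only 10 splits exist for the 3 responses and for each pair of genotypes, too few for a share under 0.05. The real split gave 10538, 10952 and 8544 genes at 6, 24 and 42 h and the highest of the others gave 0, 0 and 1. Each of these other splits mixed 0 h and stimulated arrays in both groups, so the change with time entered the spread. Counts near 0 follow from that construction, and the contrast with the real split says nothing about chance. For Tlr9 knockout against WT, Tlr7 knockout against WT and Tlr9 against Tlr7 knockout the real split gave 13, 1 and 29 genes and the highest of the others 0, and in each of these comparisons 1 split, the real one, gave as many. For the double knockout, 100 drawn splits were counted, and as the real split gave 0 genes (limma, 4382 at an unadjusted p under 0.05), all 100 had to give as many, so this count says nothing about chance. The highest of the others, with 490 genes, grouped the 24 h arrays of WT, the Tlr7 knockout and the Tlr9 knockout. With time as a term it compares these with the double knockout 24 h array alone, so it points to a structure of the arrays, and what drives it was not tested.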
